A study of Mus musculus with 4 samples.

How the data were processed

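The data came from 4 Affymetrix Mouse430_2 arrays of sorted tumor endothelial cells, 1 for each of 2 clone classes in each of 2 tumors. Per the labels' protocols, RNA was extracted with TRIzol, amplified in 2 rounds and labelled with biotin. The deposited values were on a log2 scale and came from RMA with the affy package, per the submitters' processing notes; the versions and the probe set definition were not given in the sources used here. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a probe set, so a gene's level on 1 array depends on the other arrays too. Amplification before labelling favours the 3 prime ends of transcripts and can enlarge differences between samples of little RNA.

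Clone class and tumor were taken from the labels, with the 2 replicates of a class coming from tumor A and tumor B. Since the same-numbered arrays came from the same tumor, the labels pair them. As a check, the deviations of same-numbered arrays from their class means correlated at r = -0.661 over 18193 genes, where a shared tumor effect would give a value above 0. The arrays are biological replicates by their titles, but n is 2 per class, so the p-values measure the spread between these arrays only.

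Of 45101 probe sets, 64 controls were set aside and 45037 were tested. Gene names came from the platform annotation, updated through gene IDs with a RefSeq table of the GRCm38.p6 assembly, which changed 0 symbols: 34945 tested probe sets had 1 symbol, 932 had several and were not named, and 9160 were not listed there. Of those with 1 symbol, 34741 had a gene ID in the RefSeq table. No coordinates are given, since no genome build is tied to the array values. Where 1 value per gene was needed, the probe set with the highest mean over the 4 arrays stood for the gene, and 9010 of 18193 genes had more than 1. Among 37 genes named for the size of their difference or fixed by name, 25 had more than 1 probe set, and in 16 of these at least 1 dimmer probe set had another combination of signs in the 2 tumors. These were Acss1, Ms4a6d, Lif, Inhba, Cenpe, Zmynd19, Ptprc, Hgf, Vegfa, Pdgfb, Fasl, Cd244a, Car3, Pgr, Cd53 and Olfr78. Of the genes named for a list, Kif23, Cdc20, Uhrf1, Ak4, Cspg4 and Hk1 also had such a probe set.

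Differences between clone classes and between tumors were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 2 residual degrees of freedom and a prior of 1.45 for the clone classes and 1.49 for the tumors. Benjamini-Hochberg adjustment ran over all 45037 probe sets, with a threshold of 0.05. Within a tumor there is 1 array per class, so differences there were counted at 2-fold without a test. Gene lists, 18 of cell type markers and 29 of programs, were tested with camera (inter-gene correlation preset at 0.01) where at least 5 genes were measured, with adjustment over the 47 lists. Of 830 distinct list genes, 761 were measured, and the other 69 were not analysed here. Camera with an estimated correlation and fry, a rotation test of whether a set moves in 1 direction, were the alternatives. A list's median within a tumor was placed among 10000 random lists of the same size matched on expression level in 20 bins.

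The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule named up to 12 genes per direction for the clone classes and up to 6 for the tumors, by the size of the mean difference among genes past the threshold. Places left were filled with genes at least 2-fold apart the same way in both tumors (or both classes) and with a mean in the higher group at or above the median of all probe sets, 5.83. Symbols that are only clone or model names were left out, which kept out 5530601H04Rik. It also named up to 3 genes per list with the same sign in both tumors, and 12 genes fixed by name, from Pecam1 to Cd244a. Members of a list shown for opposite differences, such as Dct, Tyr, Gbp2 or Mcm2, were picked after their values were seen.

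The alternatives were tumor as a replicate block, clone class as a term between the tumors, only probe sets at or above the median level, quantile normalization again, subtraction of array medians, eBayes with trend and robust estimation, the mean of a gene's probe sets, a 1.5-fold threshold, and leaving out each array in turn. A crossed pairing of the arrays and the array's mean over the melanoma list as a covariate were added after seeing the data. The limma step was tested on simulated data with the spread of the real arrays, over 45037 probe sets. For the clone comparison it called 0 of 50 probe sets changed by 1 on the log2 scale, 0 of 50 changed by 2, 16 of 50 changed by 3 and 31 of 50 changed by 4, with 1 false call among 44837. In the list test over 18193 genes, 4 of 5 lists shifted by 1 and 0 of 30 unshifted lists were called. Each simulated gene was drawn independently, so these counts do not cover false calls where the genes of a list move together, as they did here.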

Results

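Gene expression was measured in endothelial cells of B16 melanoma, a transplantable pigmented tumor line of C57BL/6 mice, grown in mice that carried a multicolor Cre reporter. In such mice tamoxifen switches cells and their descendants to 1 of several colors, so that cells of 1 color can be treated as a clone. Unrelated cells can take the same color, so cells of 1 color need not be a single clone. Tumors were dissociated 2 weeks after inoculation, and cells negative for CD45 and positive for CD31 and CD144 were sorted, a gate for endothelial rather than blood cells. From each of 2 tumors, A and B, the most frequent clone (expansion) and the least frequent clone (extinction) gave 1 array each, so that each clone class had 2 arrays and each combination of class and tumor had 1. The 4 Affymetrix arrays held log2 RMA values for 45101 probe sets, with array medians between 5.73 and 5.83. Of these, 45037 were tested and stood for 18193 named genes. Arrays carry no read depth, and their number limits the precision here.

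The first comparison asked how the most frequent clone differed from the least frequent clone. No probe set passed the test, and few genes differed in the same direction in both tumors. The chemokine receptor Cxcr4, a marker of sprouting tip cells, had the largest difference among genes at least 2-fold apart the same way in both. Its log2 level was 6.51 and 7.37 in the expansion arrays of tumors A and B and 10.34 and 8.99 in the extinction arrays, a mean difference of -2.73 ± 0.62 (SE, n = 2 per class). The potassium channel subunit Kcne3, also on the tip cell list, differed by -1.96 ± 0.46 (SE), and the matrix glycoprotein tenascin C (Tnc) by -1.57 ± 0.41 (SE). Inhba, which encodes the activin A subunit, differed by -1.47 ± 0.48 (SE), and the cytokine Lif by -1.60 ± 0.38 (SE).

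Further genes that were lower in expansion in both tumors were Tmem255a, at -2.16 ± 0.38 (SE), Tafa2, at -2.04 ± 0.52 (SE), Ms4a6d, at -1.91 ± 0.28 (SE), and Cped1, at -1.47 ± 0.68 (SE). Ltbp2, a microfibril-associated protein that resembles the latent TGF-beta binding proteins, differed by -1.43 ± 0.84 (SE). The kinetochore motor Cenpe differed by -1.23 ± 0.16 (SE) and Zmynd19 by -1.10 ± 0.14 (SE), with nearly the same size in each tumor (-1.10 and -1.11 for Zmynd19). The other 2 of the 14 lower genes, Mgarp and the cohesin acetyltransferase Esco2, were named after their values were seen; Esco2 was at 3.93 and 3.74 in expansion and 5.76 and 5.53 in extinction. Of the 2 higher genes, Acss1, a mitochondrial acetyl-CoA synthetase, differed by 1.26 ± 0.48 (SE). The other, the clone-named 5530601H04Rik, was also picked after its values were seen and was at 8.11 and 7.21 in expansion and 7.10 and 6.04 in extinction.

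None of these genes passed limma's test with Benjamini-Hochberg adjustment over the 45037 probe sets (adjusted p = 1 for each). It called 0 probe sets higher and 0 lower, and 469 had an unadjusted p under 0.05, where 2252 would be expected by chance alone. Counting genes at least 2-fold apart, 1072 were higher and 1897 lower in expansion within tumor A, and 1761 higher and 867 lower within tumor B. Only 2 were higher in both tumors and 14 lower in both, against 103.8 and 90.4 expected if the tumors were independent, while 1598 differed 2-fold in opposite directions. Both expansion arrays lay on 1 side of both extinction arrays for 20.7% of genes, where chance gives 33.3%. Averaging all probe sets of a gene left 0 genes higher in both tumors and 8 lower.

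Among the 47 gene lists fixed beforehand, 5 fell in expansion and 1 rose by limma's camera test with a preset inter-gene correlation. None of the 6 calls held with an estimated correlation (adjusted p = 0.982 by camera for each). All 47 lists had that same adjusted p, the correlation being estimated on 2 residual degrees of freedom. That setting thus told no list apart from another, whatever its difference. The endothelial tip cell list fell, with a median log2 difference of -0.76 over its 18 measured genes (adjusted p = 5.8e-09). Its 2 tumors differed, since the median was -1.92 in tumor A and 0.39 in tumor B, where pan-endothelial genes were lower and higher in expansion respectively. In both tumors 8 of the 18 genes were lower in expansion. They included Cxcr4, Kcne3, the endothelial proteoglycan Esm1, at -1.63 ± 0.43 (SE), and the Tie2 ligand Angpt2, at -0.83 ± 0.28 (SE). None of the 18 passed over all genes or adjusted over the list alone.

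Both cell cycle lists fell. The mitosis list had a median of -0.36 over 29 genes (adjusted p = 3.88e-09, and 0.982 with an estimated correlation), with -0.66 in tumor A and -0.23 in tumor B, and 14 of its genes were lower in expansion in both. Cenpe led it, followed by the kinesin Kif23, at -0.85 ± 0.19 (SE), and the anaphase activator Cdc20, at -0.77 ± 0.33 (SE), although for Kif23 and Cdc20 only the brightest of 3 probe sets had these signs. The proliferation marker Mki67 was at 11.28 and 10.31 in expansion and 11.38 and 11.25 in extinction. The DNA replication list had a median of -0.39 over 26 genes (adjusted p = 4.01e-08, and 0.982 with an estimated correlation). Its median was -0.24 in tumor A and -0.71 in tumor B, and 11 genes were lower in both, among them the maintenance methylation cofactor Uhrf1, at -0.92 ± 0.30 (SE), and Rfc3, at -0.87 ± 0.25 (SE). The replicative helicase genes Mcm2 and Mcm7 differed by 1.33 and 1.29 in tumor A and by -1.83 and -1.48 in tumor B, the directions of the melanoma list in those tumors. No member of either list passed over all genes or adjusted over the list alone.

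The hypoxia response list fell by a median of 0.37 on the log2 scale over 24 genes (adjusted p = 0.000388, and 0.982 with an estimated correlation), with -0.39 in tumor A and -0.42 in tumor B. In both tumors 7 genes were lower in expansion, led by the HIF hydroxylase Egln3, at -1.33 ± 0.44 (SE), the mitochondrial kinase Ak4, at -0.91 ± 0.47 (SE), and the glucose transporter Slc2a1, at -0.73 ± 0.45 (SE). The carbonic anhydrase Car9 went opposite ways, 2.89 in tumor A and -4.02 in tumor B, as the melanoma list did. The pericyte and smooth muscle list fell by a median of 0.17 on the log2 scale over 16 genes (adjusted p = 0.0282, and 0.982 with an estimated correlation). Its median was -0.84 in tumor A and 0.48 in tumor B, and 5 genes were lower in both, among them Cspg4 and Kcnj8. Averaging each gene's probe sets ended that call (adjusted p = 0.0524).

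The keratinocyte list was the one that rose, with a median of 0.22 over 11 genes (adjusted p = 0.025, and 0.982 with an estimated correlation). Its genes lay near the low end of the array scale, with a median level of 4.85, and the epithelial genes Perp and Sfn differed by 0.58 ± 0.25 (SE) and 0.35 ± 0.15 (SE). With only genes at or above the median level of all probe sets, fewer than 5 of its genes were left and it was not tested. None of the members of the hypoxia, pericyte or keratinocyte lists passed over all genes or adjusted over the list alone. In 10 lists, none of them called, the median, the mean and the direction of the test differed in sign, the melanoma list among them (median 0.07, mean -0.04). Each of the 6 calls ended without some single array: mitosis without the extinction array of tumor A (adjusted p = 0.74 by limma's camera), tip cell without the expansion array of tumor A (0.0961), and DNA replication and hypoxia without the expansion array of tumor B (0.223 and 0.133). The keratinocyte call ended without the expansion or the extinction array of tumor A (0.407 and 0.382), and the pericyte call without either expansion array (0.149 and 0.0884) or the extinction array of tumor A, where its direction turned (0.104).

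Considered tumor by tumor, the clone difference ran in opposite directions. Melanoma genes were higher in expansion in tumor A and lower in tumor B, and endothelial genes the reverse. All 14 measured genes of the melanoma list were at least 2-fold apart in opposite directions, with a median log2 difference of 4.63 in tumor A and -5.07 in tumor B. The pigment enzyme Dct and the melanosome protein Pmel were bright on expansion A and extinction B, where the array maxima were 15.03 and 14.97. The pigment enzyme Tyr was lower than both on every array. Dct was at 14.36 in expansion A, 9.79 in extinction A, 7.62 in expansion B and 13.84 in extinction B, and Tyr was at 11.85, 6.27, 4.30 and 10.55 on the same arrays. All 20 genes of the pan-endothelial list were lower in expansion of tumor A and higher in expansion of tumor B, with medians of -2.43 and 1.67. The sorting markers behaved alike: CD144 (Cdh5) was at 8.69, 11.46, 11.51 and 9.80, and CD31 (Pecam1) at 6.16, 8.82, 8.61 and 6.90, in the same array order. CD45 (Ptprc), the marker sorted against, stayed between 3.63 and 4.27.

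**Figure D1:**
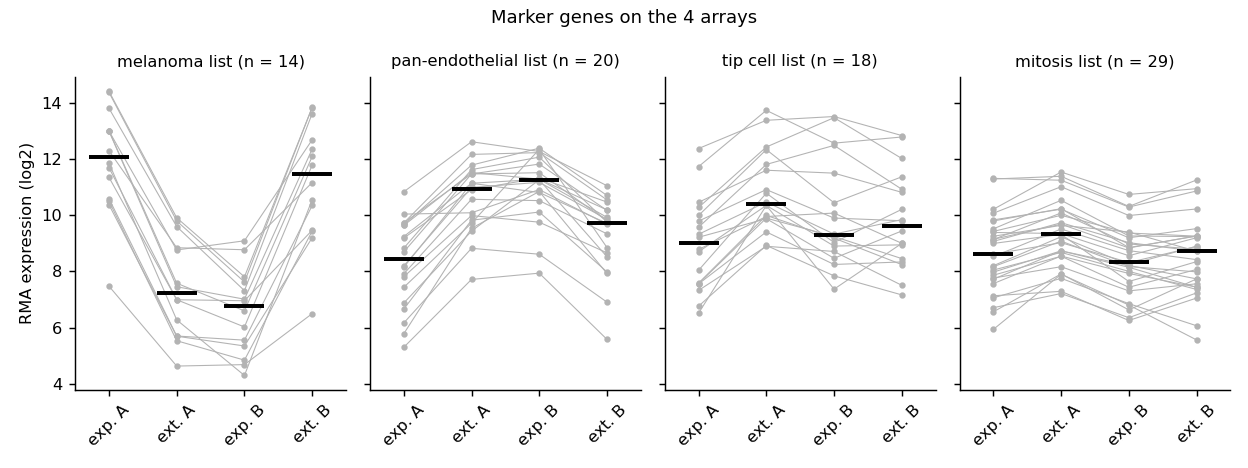
RMA log2 expression of each gene of 4 fixed lists (grey points joined per gene) on the arrays of expansion (exp.) and extinction (ext.) clones of tumors A and B, with the list median as a black bar. The melanoma medians are 12.07, 7.22, 6.77 and 11.47 and the pan-endothelial medians 8.44, 10.94, 11.26 and 9.73, so that the 2 lists run opposite to each other and cross over between the tumors.

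Other lists followed the endothelial genes. The capillary list had medians of -1.92 in tumor A and 2.17 in tumor B, the venous list -1.98 and 1.37, and the arterial list -1.57 and 1.16. Leukocyte adhesion molecules were at -1.82 and 1.32. All 26 interferon response genes were lower in expansion of tumor A and higher in expansion of tumor B, with medians of -1.28 and 0.99, and MHC class I genes had medians of -1.06 and 1.27. The interferon-induced GTPase Gbp2 differed by -1.79 and 2.25, and the chemokine Cxcl9 by -2.17 and 2.22. Fibroblast genes had medians of -1.17 and 0.96 and were bright throughout: the collagen genes Col1a2 and Col3a1 lay between 14.32 and 14.90 on every array. Cholesterol synthesis genes followed the melanoma genes, with medians of 1.39 and -1.20. Glycolysis genes, with medians of 0.51 and -0.91, did so too. Macrophage, T and NK cell, B cell, dendritic cell, neutrophil, erythroid and MHC class II lists had median levels between 4.73 and 5.85, near or below the 5.83 that was the median of all probe sets.

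Across the 18193 genes, the clone difference in tumor A correlated with that in tumor B at Pearson r = -0.731 (Spearman rho -0.602, covariance -0.492). Genes are not independent replicates, and the 2 differences share no array. Each array correlated best with the array of the other tumor and the other clone class: r was 0.983 between expansion A and extinction B and 0.980 between extinction A and expansion B, while it was 0.921 between the 2 expansion arrays and 0.958 between the 2 extinction arrays. A difference between the tumors in the clone difference was not tested, since 4 arrays leave no residual degree of freedom for it. Some control signals crossed over too: the 18S ribosomal RNA probe sets averaged 11.64, 10.77, 11.10 and 11.86, and the 5 prime probe sets of the polyadenylated spike-in controls 10.27, 9.62, 10.17 and 11.30, in the order expansion A, extinction A, expansion B, extinction B. The bioB hybridization control did not, being lower in expansion in both tumors (-0.44 and -0.84). Extinction B had the highest signal for it and for other hybridization controls. In the same array order BioC-3 was at 10.24, 10.33, 10.49 and 11.43, and BioDn-3 at 12.63, 12.57, 12.72 and 13.42. BioDn-3 thus differed in opposite directions, though little in tumor A. The 3 prime minus 5 prime differences of Actb (0.63 and 0.03) and Gapdh (0.09 and 0.31) had the same sign in both tumors.

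**Figure D2:**
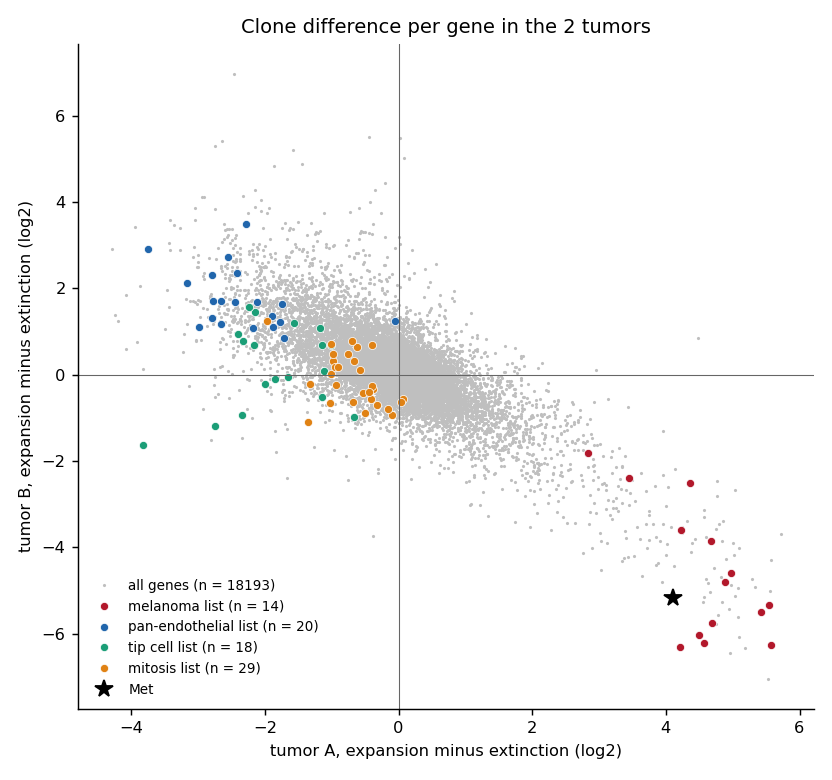
Log2 difference between expansion and extinction for each of 18193 genes (grey) in tumor A (horizontal) and tumor B (vertical), with the melanoma, pan-endothelial, tip cell and mitosis lists and Met marked. The cloud slopes downward (r = -0.731), with melanoma genes at the lower right and pan-endothelial genes at the upper left.

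**Figure D3:**
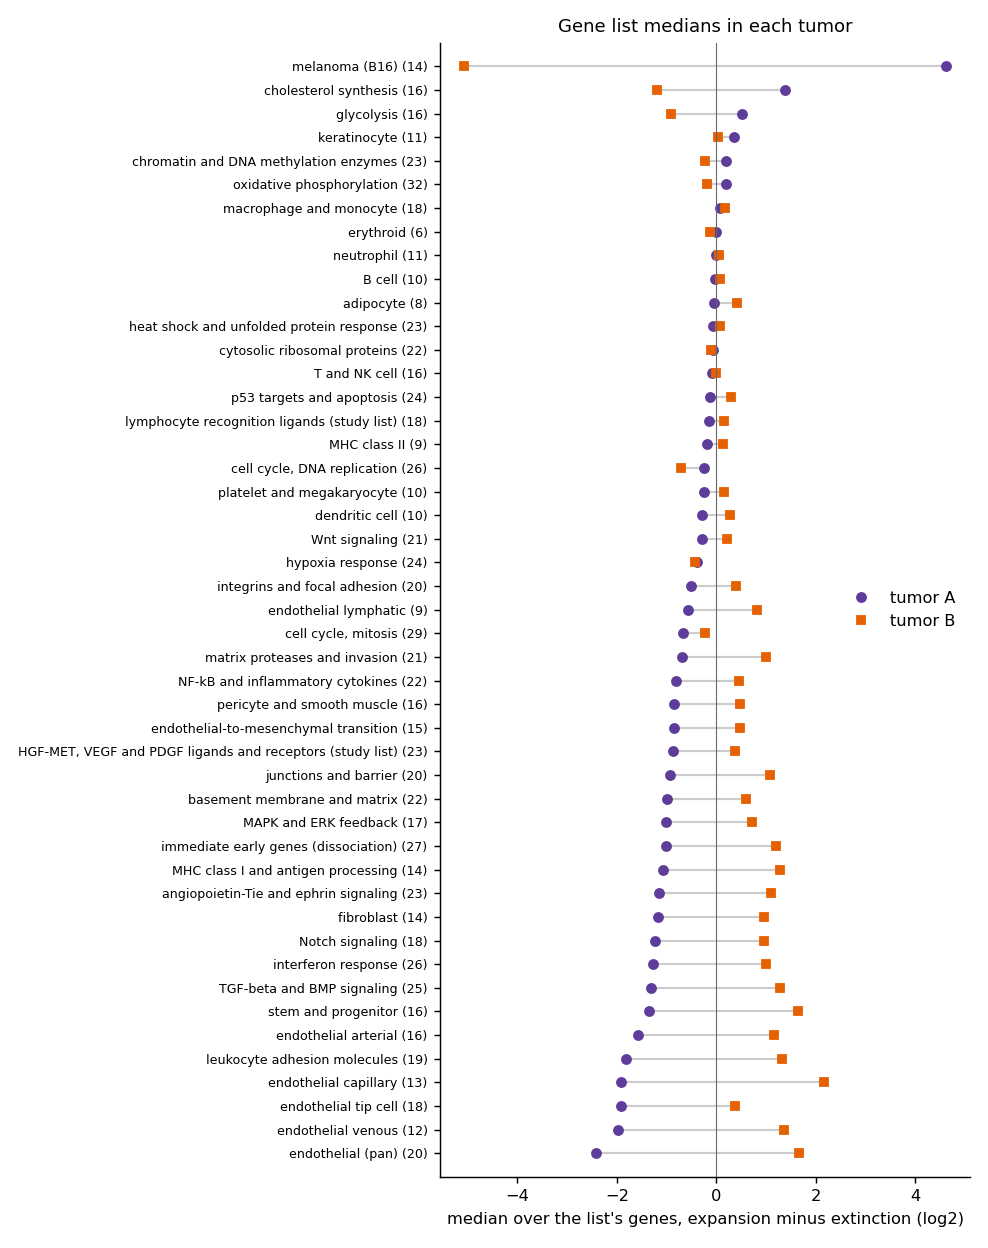
Median log2 difference between expansion and extinction over the measured genes of each of the 47 lists (number of genes in brackets), in tumor A (circles) and tumor B (squares). In 39 lists the medians lie on opposite sides of 0, while the DNA replication, mitosis and hypoxia lists lie below 0 in both tumors. So do, by less, the cytosolic ribosomal protein list (-0.065 and -0.108) and the T and NK cell list (-0.087 and -0.001).

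Growth factor receptors and lymphocyte ligands were looked at as genes recalled from the study of these samples, so their values are no independent evidence. The HGF receptor Met differed most between arrays. It was at 13.41 and 8.001 in the expansion arrays of tumors A and B and at 9.29 and 13.17 in the extinction arrays, a mean difference of -0.53 ± 2.54 (SE, n = 2 per class), smaller than its standard error. Its levels ran with the melanoma list. The VEGF receptor Kdr was at 8.82 and 12.06 in expansion and 11.62 and 9.75 in extinction, running with the endothelial list. Its ligand Vegfa differed by -0.02 ± 0.34 (SE), Pdgfa by -0.73 ± 0.30 (SE), Pdgfb by -0.73 ± 0.91 (SE) and Pdgfrb by -0.23 ± 0.52 (SE). Hgf lay between 5.09 and 5.37, Fasl between 4.02 and 4.43 and Cd244a between 4.68 and 4.72, all below the median of all probe sets.

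Neither of the 2 lists of such genes was called. The list of HGF, VEGF and PDGF ligands and receptors had a median of -0.12 over 23 genes (adjusted p = 0.201 by camera), with -0.87 in tumor A and 0.39 in tumor B. The lymphocyte ligand list had a median of -0.02 over 18 genes (adjusted p = 0.948 by camera). None of their genes passed limma's test over all genes or adjusted over the list alone. The immune checkpoint ligand Cd276 was lower in expansion in both tumors, at -1.18 ± 0.57 (SE), as was the placental growth factor Pgf, at -0.82 ± 0.36 (SE).

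The second comparison set tumor B against tumor A, across clone classes. Genes higher in tumor B in both classes included dermokine (Dmkn), by 2.87 ± 0.25 (SE, n = 2 per tumor), suprabasin (Sbsn), by 1.83 ± 0.24 (SE) and the keratin Krt23, by 1.66 ± 0.27 (SE). The acute phase gene Saa1 differed by 2.901 ± 0.58 (SE) and the progesterone receptor Pgr by 2.32 ± 0.73 (SE). Carbonic anhydrase 3 (Car3) differed by 4.88 ± 1.91 (SE), with 11.49 in expansion B and 6.46 in extinction B. Lower in tumor B were the retinoic acid binding protein Crabp1, at -2.54 ± 0.24 (SE), the epidermal Sprr2h, at -2.66 ± 0.59 (SE), the granzyme Gzme, at -2.15 ± 0.32 (SE), the protease Mmp10, at -2.26 ± 0.88 (SE), the leukocyte tetraspanin Cd53, at -1.68 ± 0.57 (SE), and the olfactory receptor Olfr78, at -1.58 ± 0.45 (SE).

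None of these passed limma's test (adjusted p = 1 for each), which called 0 probe sets higher and 0 lower in tumor B. The smallest adjusted p by limma over the 45037 probe sets was 0.284, and 648 had an unadjusted p under 0.05. In both clone classes, 13 genes were at least 2-fold higher and 10 at least 2-fold lower in tumor B, a total of 23 against 16 for the clone classes and 1598 for the third way of pairing off the 4 arrays.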

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

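All tests of explanations in this part were chosen after the values had been seen, and the criteria for an exchange of arrays and for 3 prime bias were rewritten after their first outcomes were seen. In 23 of the 47 lists the clone difference had opposite signs in tumor A and tumor B and lay outside the central 95% of random lists in both; with 1 array per class and tumor, this difference between the tumors was not tested. The melanoma list stood out most, its median difference in tumor A exceeding that in tumor B by 9.69 on the log2 scale. The value was 2.58 for cholesterol synthesis, 1.42 for glycolysis and 0.38 for oxidative phosphorylation. It was -4.09 for both the pan-endothelial and the capillary list (-4.092 and -4.089), -3.35 for venous, -2.73 for arterial and -1.38 for lymphatic endothelium, -2.13 for fibroblasts and -3.002 for stem and progenitor genes. Leukocyte adhesion molecules were at -3.14, MHC class I at -2.33, the interferon response at -2.27, and NF-kB and inflammatory cytokines at -1.28.

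Among signaling lists the same quantity was -2.18 for Notch, -2.24 for angiopoietin-Tie and ephrins, -2.59 for TGF-beta and BMP and -1.74 for MAPK and ERK feedback. It was -2.21 for immediate early genes, -1.57 for basement membrane, -1.68 for matrix proteases and -2.01 for junctions. Of the genes fixed by name, Pecam1 was at -4.36, Cdh5 at -4.48, Kdr at -5.11 and Met at 9.29, again without a test of the difference.

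The opposite melanoma and endothelial differences were weighed against 3 technical explanations. RNA degradation or 3 prime bias stays open in part. The 3 prime minus 5 prime differences of 4 of 6 control transcripts, all spike-ins, crossed over, by up to 1.13. The smallest melanoma difference was 1.81. Spike-ins are added RNA, so their crossing concerns amplification or labelling and cannot show degradation of the cells' own RNA. For Actb (0.63 and 0.03) and Gapdh (0.09 and 0.31), transcripts of the cells, the differences did not cross. These 2 transcripts argue against degradation as the cause, while a bias from amplification stays open. RNA of melanoma genes was abundant on 2 arrays. On expansion A and extinction B the melanoma list medians, 12.07 and 11.47, exceeded the pan-endothelial medians, 8.44 and 9.73. A differing share of B16 cells or their RNA among the sorted cells may thus account for the crossing. All 14 measured melanoma genes, 0 of which are in another list, moved together, up to the level of Pmel at 14.40. They moved against the endothelial, pericyte and fibroblast medians. A gate on CD31 and CD144 is meant to remove such cells, but fibroblast list medians lay between 10.69 and 12.72 on the 4 arrays. The sorted material may thus hold RNA of other cells, and the gate is weak evidence against B16 cells. An exchange of the 2 arrays within 1 tumor could produce the crossing as well. Arrays of other tumor and other class correlated better than arrays of the same class by at least 0.0211. These correlations do not say which tumor. An exchange alone would leave the high melanoma levels themselves unexplained, and an exchange together with B16 RNA was not tested. A clone difference that truly depends on the tumor predicts the same correlations between arrays and stays open, untested. By itself it does not predict the crossing of the spike-ins, and neither does a differing share of B16 RNA.

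The tip cell, cell cycle and hypoxia lists were lower in expansion on average. A differing share of B16 RNA may account for part of this. For the mitosis list that share predicts opposite signs in the tumors. Its median was instead below 0 in both, at or under percentile 0.93 of random lists in each tumor. Random lists take genes as independent and measure no error between arrays. Of its 29 genes, 13 were lower in expansion of tumor A and higher in that of tumor B, and 2 the reverse. The percentiles thus cannot decide whether that share was the whole cause. For DNA replication and hypoxia the question stays open too, because their tumor A medians sat inside the random range, at percentiles 20.1 and 9.23. A differing endothelial share would move tip cell and pan-endothelial genes alike. The tip cell median departed from the pan-endothelial one by 0.50 in tumor A and by -1.28 in tumor B. The standard errors over genes, 0.25 and 0.28, are those of a difference of means. They take genes as independent and measure no error between arrays. Since other cells also express genes of the tip cell list, this explanation too stays open. With each array's melanoma mean as a covariate, the tip cell, mitosis, DNA replication and hypoxia lists passed with the preset correlation (adjusted p = 8.19e-12, 1.05e-06, 1.23e-07 and 4.89e-05 by limma's camera), as did the pan-endothelial list, lower in expansion (3.33e-05, against 0.369 without the covariate), while none passed without it at adjusted p = 0.982 with an estimated correlation, which was not run with it. That mean was nearly equal in expansion and extinction (9.27 and 9.30). The covariate therefore moved the 4 medians by at most 0.011 and decides little. A clone class effect remains open. A lower endothelial share in expansion remains open for tumor A only. In tumor B all 20 pan-endothelial genes were higher in expansion, while the mitosis, DNA replication and hypoxia medians were lower (-0.23, -0.71 and -0.42).

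Met, a gene of the study, went with the melanoma list. Its differences of 4.11 and -5.17 lay within the range of the melanoma genes (2.84 to 5.58 in tumor A, -6.30 to -1.81 in tumor B) in 2 of 2 tumors, so Met transcripts from B16 cells are a candidate explanation. Had Met followed the endothelial share, it would lie between -3.75 and -0.05 in tumor A and between 0.86 and 3.49 in tumor B, which it did in 0 tumors. Regulation of Met by clone class within endothelial cells was not tested and stays open.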

How the results depend on the processing

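No probe set passed between clone classes or between tumors under any alternative, including tumor as a replicate block (0 higher, 0 lower), each array left out in turn (the lone array of a class or tumor assumed to vary like the others) and the melanoma covariate, chosen after seeing the data. The crossed pairing, also chosen afterwards, gave 0 probe sets higher and 0 lower, and 2 lists higher and 7 lower. On simulated arrays changes of 1 or 2 on the log2 scale were not called at this spread, so the counts of 0 exclude little.

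Genes higher in expansion in both tumors numbered 2, and 47 at 1.5-fold; they were 1 with only genes at or above the median level, 1 after quantile normalization, 1 with array medians subtracted and 0 with the mean of probe sets. Those lower numbered 14, 64 at 1.5-fold and 8 with the mean of probe sets. The correlation of the 2 tumors' differences was -0.767 for genes at or above the median level. Otherwise it stayed within its interval of -0.738 to -0.724. That interval takes genes as independent replicates, which they are not, so it is only a yardstick. The changes at 1.5-fold and at or above the median level follow from the threshold and the genes kept. For the normalizations and the mean of probe sets the cause was not tested.

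Lists higher in expansion numbered 1, and 0 with an estimated correlation, 0 with fry, 0 with genes at or above the median level, where 8 lists, the keratinocyte list among them, kept fewer than 5 genes and were not tested, 2 with array medians subtracted, 2 with the melanoma covariate and 0 to 17 with an array left out. Lists lower numbered 5, and 0 with an estimated correlation, 0 with fry, 8 with the melanoma covariate and 4 to 22 with an array left out; the cause was not tested. Without the expansion or extinction array of tumor A the counts were 17 and 8 or 0 and 4, and without those of tumor B 5 and 22 or 2 and 13. Tumor as a replicate block changed no list call and no other call. With an array left out, the fits over all probe sets served only for counts, and no values of single genes are given. Under the other alternatives Hk1 changed sign, from 0.086 to -0.066 with the mean of its probe sets; the cause was not tested. Genes opposite in the 2 tumors depend on the array kept: Met was at 13.41 and 8.001 in expansion around an extinction mean of 11.23, and Kdr at 8.82 and 12.06 around 10.68.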

Other observations

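Apart from the comparisons above, 3 sets of values stood out, all picked after they were seen and none of them tested for a cause. The expansion array of tumor B carried genes at higher levels than the other 3 arrays. The fat cell hormone adiponectin (Adipoq) was at 6.78 against 3.75 to 3.78, the corneal and tendon proteoglycan keratocan (Kera) at 9.47 against 3.847 to 3.996, the progenitor marker Prom1 at 9.63 against 4.12 to 5.27 and Cd24a at 9.99 against 5.56 to 6.80. The adipocyte list had a median difference of 0.43 in tumor B, at percentile 99.2 of random lists, and -0.05 in tumor A.

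The Y chromosome genes Eif2s3y, Kdm5d and Uty differed in the same directions as the pan-endothelial genes. Eif2s3y was at 6.77 in expansion A, 8.83 in extinction A, 9.13 in expansion B and 7.71 in extinction B. On the same arrays Kdm5d was at 4.86, 6.79, 7.11 and 5.09, and Uty at 4.49, 6.05, 6.16 and 5.57. For Uty the difference in tumor B, 0.59, lay below the pan-endothelial range there of 0.86 to 3.49. Xist, the transcript of the inactive X chromosome, stayed between 5.39 and 5.60 on all 4 arrays.

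In list tests between the tumors, chosen after seeing the data, 12 of the 47 lists were called by camera with the preset correlation and 0 with an estimated one. The mitosis list was lower in tumor B by a median of 0.49 on the log2 scale over 29 genes (adjusted p = 7.28e-09 by limma's camera, and 0.978 with an estimated correlation), with array medians of 8.61 in A and 8.31 in B for expansion and 9.32 and 8.71 for extinction. The interferon response and capillary lists were called higher there (adjusted p = 4.22e-05 and 0.0015 by limma's camera, and 0.978 with an estimated correlation), but went opposite ways in the clone classes, as the pan-endothelial list did. Interferon medians were 8.46 in A and 10.41 in B for expansion and 9.97 and 9.10 for extinction, and capillary medians 7.66 and 11.94, and 10.19 and 9.22. Both arrays with high melanoma signal carried the same second code in the labels' descriptions, P4, whose meaning the labels do not give; the other arrays carried P8 and P20.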
